A study of Mus musculus with 15 samples.

How the data were processed

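Gene expression was measured by RNA sequencing in 15 libraries of cultured mouse neural progenitor cells. Per the labels, the input was ribosomally bound RNA, libraries came from a stranded mRNA kit, and single reads of 75 cycles were taken on a NextSeq500. The labels also give the molecule as total RNA, and they do not say how ribosomally bound RNA was obtained. Groups were taken from the genotype and time labels, with 3 wild type and 3 knockout-labelled libraries at 0 h, and 4 wild type and 5 knockout-labelled libraries at 48 h. Labels do not state whether libraries are separate cultures, so p-values measure only the spread between these samples.

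The deposited count table holds expected counts, that is, estimated counts per gene that are not all whole and are not scaled for depth. The deposited abundance files hold expected counts and TPM, each transcript's share of all transcripts, for 133944 transcripts per library. Per the labels, the authors used bcl2fastq 2.20 and STAR with the builds GRCm38 and mm10, but the role of each is not stated, nor is the tool that wrote the abundance estimates. The count table equalled the abundance files' estimates summed per gene within 0.5 for 99.6% to 99.8% of genes in each library. Its 25 columns include 10 that belong to no labelled sample, and these were not used. Gene symbols and positions came from the GENCODE annotation of GRCm38, which matched 36285 of the 36387 genes by identifier.

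Totals per library ran from 9830644 to 25430861 counts. Counts were rounded, and genes with low counts were removed with edgeR's filterByExpr by group, which left 18375 genes. Libraries were scaled with TMM factors, and CPM values (counts over the library's scaled total) are on that scale. A quasi-likelihood model with 1 term per group was fitted to all 15 libraries at once (edgeR 4.0.16 in R 4.3.3). Contrasts gave the genotype effect at 0 h and at 48 h, the time effect in each genotype, and the difference between the time effects. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic, and standard deviations (SD) are between libraries of a group. For genes with no counts in a group, a lower bound of the fold was set at 3 counts over the whole group. With 1 to 3 counts, the ratio is given with its exact 95% binomial interval. Intervals and floors cover counting error only.

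Before the data were examined, 45 gene lists, the comparisons, the named-gene rule and most alternatives were fixed. In 43 lists at least 3 members passed the filter, and the erythroid and Hox lists had fewer. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison. Beside it were camera with an estimated correlation and fry, which tests the members alone and not against other genes. Medians of lists with members at 0 counts in 1 group were recomputed with those members at their bound. Named genes are Bcl7a and any called BAF subunit, then up to 8 called genes per direction with the largest change. These 8 needed a mean log2 CPM of at least 1, groups that do not overlap (not asked of the interaction) and a symbol that is not that of a predicted gene. Up to 2 called members per direction of each list, sex-linked genes and the most abundant markers of other cell types complete the rule. Bcas1, Mag and the per-library values shown for myelin genes at 48 h were chosen after their values were seen.

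The test was checked on simulated counts with the real means, library sizes and spread, in which 200 genes were changed. At 0 h, edgeR recovered 9% of genes changed by a log2 of 1 and 53% of those changed by a log2 of 2, with 1 false call among 17538 genes. DESeq2 recovered 24% and 71% with 65 false calls. At 48 h, edgeR recovered 34% and 63% with 1 false call, and DESeq2 52% and 80% with 56 false calls among 17560 genes. For the interaction, edgeR recovered 2% and 36% with 4 false calls among 17517 genes. Camera at the preset correlation called the shifted list and 0 of 40 random lists. Simulated genes varied independently, so this does not test the preset value. In the real data the estimated correlation was higher in many lists, such as 0.447 for cytosolic ribosomal proteins at 0 h.

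Alternatives covered the scaling (DESeq2 size factors, upper-quartile factors), the test (DESeq2 1.42.0, limma-voom, voom with sample quality weights), and the low-count filter (none, or at least 50 counts in at least 3 libraries). Others were the count source, a 2-fold threshold, a fit of only the groups compared, removal of sex-linked and Y genes, and leaving out each library. Consecutive sample numbers at 0 h and 48 h were also tried as 6 blocks of 12 libraries. Deviations from group means correlated at 0.104, 0.222 and 0.135 in the wt pairs, 2 of them above any other match, and at 0.126, -0.066 and -0.051 in the knockout-labelled pairs, none above. The presence of Y-linked transcripts agreed in all 3 knockout-labelled pairs, as in 10% of 60 possible pairings. Whether such pairs share a culture is therefore open, and the unblocked fit treats them as separate. Sets chosen after seeing the data were a fit without the 2 libraries with the fewest genes, a term for Y-linked transcripts, a robust fit, and the same 12 libraries with no block.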

Results

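The libraries profile mouse neural progenitor cells, called eNPCs in the sample titles and primary NPCs in the cell type field, labelled wild type (wt) or Bcl7a knockout. Bcl7a encodes a subunit of BAF (SWI/SNF) chromatin remodelling complexes, and the series asks how its loss affects progenitors and their mitochondrial energy metabolism during differentiation. Undifferentiated cells (0 h) gave 3 wt and 3 knockout-labelled libraries, and cells after 48 h of differentiation gave 4 and 5. Total counts were between 9830644 and 25430861 per library. Time separated the libraries along the first principal component, which held 50.2% of the variance of the 500 most variable genes. The second held 21.6% and set apart 2 knockout-labelled libraries, replicate 2 at 0 h and replicate 2 at 48 h. These had 12508 and 13902 genes with a count above 0, against 20446 to 25601 in the other 13. In them, the 100 most abundant genes took 36.9% and 26.9% of counts, against 25% or less elsewhere.

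Bcl7a RNA was not lower in the libraries labelled knockout. At 0 h, Bcl7a (ENSMUSG00000029438.9, GRCm38 chromosome 5, 123343834 to 123374992) was at 73.1 ± 5.45 CPM in wt (SD, n = 3) and 105.2 ± 31.4 CPM in knockout-labelled cells (n = 3). At 48 h it was at 129.9 ± 15.1 CPM (n = 4) and 136.0 ± 22.7 CPM (n = 5). The log2 fold change between genotypes was 0.53 ± 0.21 (SE, adjusted p = 0.307) at 0 h and 0.07 ± 0.17 (adjusted p = 1) at 48 h. Whole-gene counts do not test a small deletion or a change of the protein, so the genotype is taken from the labels.

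Y-linked transcripts were present in some knockout-labelled libraries and in no wt library. Ddx3y, Uty, Kdm5d and Eif2s3y together reached 253.7 CPM in replicate 1 at 0 h and 372.4, 388.8 and 272.7 CPM in replicates 1, 4 and 5 at 48 h, against 4.78 CPM or less in the other 11. Xist, the RNA of the inactive X chromosome, was at 2.24 CPM or less in those 4. Genotype comparisons therefore also differ in the sex of the cells.

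**Figure D1:**
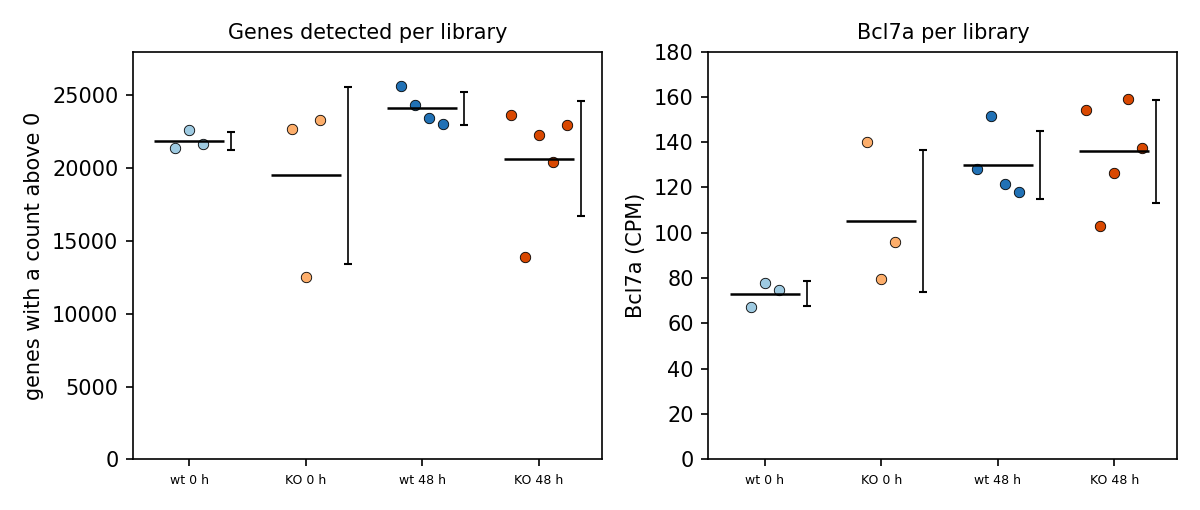
Genes with a count above 0 (left) and Bcl7a in CPM (right) for each library, with wt and knockout-labelled (KO) groups at 0 h and 48 h. Points are libraries, bars are means and whiskers are the SD. Single KO libraries at 0 h (12508 genes) and 48 h (13902 genes) lie below the rest, and Bcl7a is not lower in KO libraries.

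The first comparison asks how undifferentiated knockout-labelled cells differ from wt. Some glial and Notch pathway genes were higher in them, and Myc was lower. As lists, astrocyte, oligodendrocyte and Notch genes lost their calls with an estimated correlation (adjusted p = 0.482, 0.680 and 0.156). Gfap, the intermediate filament of astrocytes, was at 32.8 CPM against 0.457 CPM in wt, a log2 fold change of 6.12 ± 1.28 (SE, adjusted p = 0.0467), but ranged from 1 to 84.4 CPM among the 3 knockout-labelled libraries. Gpr17 (ENSMUSG00000052229.5, chromosome 18, 31942997 to 31949636), a receptor of oligodendrocyte precursors committed to differentiate, was at 13.4 ± 3.22 against 1.54 ± 0.127 CPM (SD, n = 3 each), a log2 fold change of 3.12 ± 0.23 (SE, adjusted p = 1.28e-05). Myc (ENSMUSG00000022346.15, chromosome 15, 61985391 to 61990374), a growth-promoting transcription factor, fell by 1.45 on the log2 scale (SE 0.17, adjusted p = 0.00355), from 132.9 ± 12.2 to 48.7 ± 1.96 CPM.

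In all, 79 genes were higher and 15 lower by edgeR, and 69 and 8 of these by at least 2-fold. This balance depends on the test and the libraries: limma-voom called 6 higher and 23 lower, and edgeR without the 2 libraries with the fewest genes 160 and 119. In 93 of the 94, all knockout-labelled libraries lay on 1 side of all wt libraries, as in 17.6% of tested genes and 10% by chance. Other higher genes were the long noncoding RNA Miat (log2 fold change 4.28, adjusted p = 0.00633), Srcin1 (5.29), Synpo2 (0.417 to 10.2 CPM in the mean), Ndrg2 (3.53), the water channel Aqp4 (3.53), Padi2 (3.48) and the oligodendrocyte transcription factor Sox10 (3.07). Levels varied between the 3 knockout-labelled libraries, from 0.62 to 12.9 CPM for Srcin1 and 2.01 to 25.8 CPM for Synpo2 (both highest in replicate 2, with few genes detected), and from 18.1 to 212.0 CPM for Ndrg2 (highest in replicate 1). Also higher was Id4 (2.52), an inhibitor of basic helix-loop-helix factors. Lower genes were Klf3 (-1.40), Pprc1 (-1.21), Mat2a (-1.18), Golph3 (-1.12), the nucleolar GTPase Gnl3 (-1.12), Olig2 (-1.02) and the ribosome assembly factor Rrs1 (78.0 to 39.0 CPM).

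Among the lists, astrocyte markers passed as higher, with 3 of 18 members called (8 adjusted over the list alone) and a median of 0.85, but not with an estimated correlation (adjusted p = 0.482). That median was 0.79 with a member at 0 counts set to its bound. Clu, a secreted chaperone, rose by 2.46. Notch pathway genes also passed, with 12 higher and 8 lower (3 of 20 called, 6 adjusted over the list alone), but not with an estimated correlation (adjusted p = 0.156). Called members included the effector Hes5, which rose from 12.4 to 107.9 CPM (log2 fold change 3.13 ± 0.57), and the ligand Dll3 (1.84). The oligodendrocyte list passed as higher with 8 of 16 members higher, Gpr17 and Sox10 up and Olig2 down, 5 up and 1 down adjusted over the list alone, but not with an estimated correlation (adjusted p = 0.680). Progenitor markers passed with 1 of 22 called and 4 adjusted over the list alone. The adjusted p of the progenitor list was 0.156 with an estimated correlation. This smallest value was shared with the lists of Notch, mitochondrial dynamics, fatty acid oxidation, and OXPHOS complex II and III genes.

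Several lists of energy metabolism and ribosomal genes were higher by small amounts, and none held with an estimated correlation (adjusted p of 0.156 or more). The median of OXPHOS and ribosomal genes lay 0.478 above that of all tested genes. Relative to a trend on transcript length and level, fitted to other protein-coding genes, their median was -0.0644. Mitochondrial biogenesis genes were lower in 17 of 25 (adjusted p = 0.240, with Pprc1 called), and OXPHOS assembly factors were higher in 23 and lower in 19. All 13 tested subunits of OXPHOS complexes II and III were higher (median 0.42, 0 called, 4 adjusted over the list alone), as were 32 of 36 of complex I (median 0.38, 1 called), 12 of 14 of complex IV (0.34) and all 18 of complex V (0.27). Without knockout-labelled replicate 1 the complex IV list turned direction (mean -0.452, adjusted p = 0.885), and the median of OXPHOS and ribosomal genes went from 0.354 to 0.180. Fatty acid oxidation genes were higher in 18 of 18 (median 0.44, 1 called) and cytosolic ribosomal proteins in 75 of 83 (median 0.33, 0 called). The called members were Ndufv2, a complex I subunit (133.6 to 257.4 CPM, log2 fold change 0.95), and Eci2, an enoyl-CoA isomerase (0.96). Adjusted p with an estimated correlation was 0.284 for complex I, 0.156 for II and III, 0.823 for IV, 0.357 for V, 0.156 for fatty acid oxidation and 0.364 for ribosomal proteins. Lists of TCA cycle (4 higher adjusted over the list alone), glycolysis, mitochondrial dynamics, mitochondrial ribosomal and mitochondrially encoded genes also passed as higher, with 0 called. Their adjusted p with an estimated correlation was 0.219, 0.357, 0.156, 0.624 and 0.821 in that order. Immediate early genes (11 of 14, median -0.92) and cell cycle genes (23 of 28, median -0.29) passed as lower, with 0 called. Both had an adjusted p of 0.624 with an estimated correlation.

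The 0 h calls depend on the fit and on single libraries. Fitted on only the 6 libraries compared, edgeR called 0 genes at an adjusted p under 0.05, DESeq2 called 779 and limma-voom 29 on all 15, and leaving out single libraries gave 2 (without wt replicate 1) to 670 (without knockout-labelled replicate 3).

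**Figure D2:**
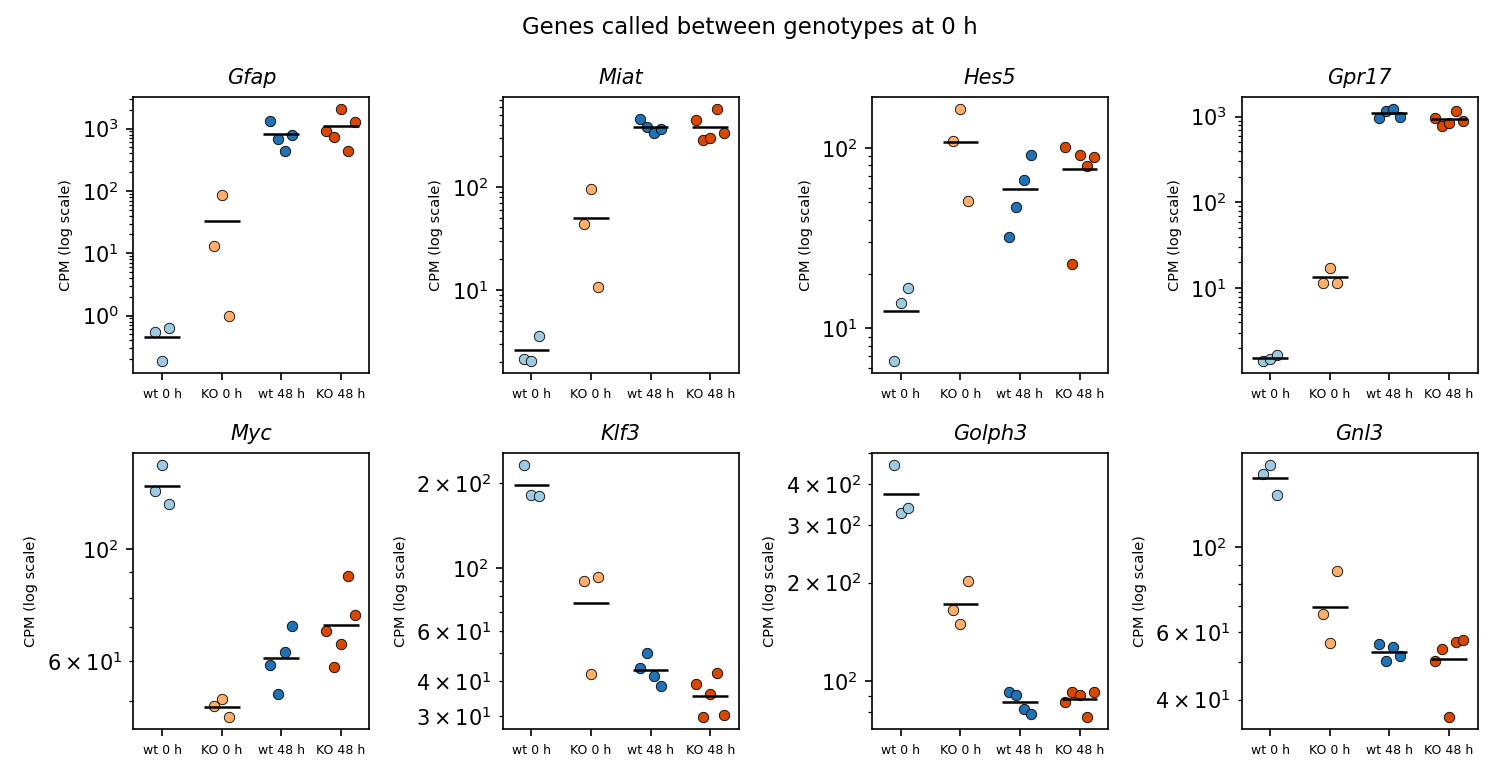
CPM on a log axis for 8 genes called between genotypes at 0 h, in wt and knockout-labelled (KO) libraries at 0 h and 48 h. Points are libraries and bars are means. Gpr17 averaged 1.54 in wt and 13.4 in KO libraries at 0 h, and 1086 and 929 at 48 h.

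The second comparison asks the same after 48 h of differentiation. Oligodendrocyte lineage markers were lower as a list in knockout-labelled libraries, with no member called, and the list's call is lost with an estimated correlation (adjusted p = 0.451). Of the 16 oligodendrocyte lineage markers, 12 were lower (median -0.67, camera adjusted p = 2.2e-05), 0 were called over all genes and 6 were lower adjusted over the list alone. These were Cnp, Plp1, Bcas1, Mbp, Enpp6 and Mag, all made in myelinating or newly formed oligodendrocytes. Mbp, myelin basic protein, was at 948.0 ± 580 CPM in wt (SD, n = 4) and 129.4 ± 129 CPM in knockout-labelled libraries (n = 5). Plp1 was at 2283 ± 966 and 714.4 ± 346 CPM, and Cnp at 1123 ± 330 and 557.4 ± 70.6 CPM. The adjusted p over all genes was 0.779 for Mbp, Plp1, Cnp, Bcas1 and Enpp6.

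The wt libraries were not uniform in these genes. Wt replicate 4 held 138.7 CPM of Mbp and 856.0 CPM of Plp1, within the range of the knockout-labelled libraries (15.3 to 347.0 and 410.8 to 1252 CPM), whereas the other wt libraries held 992.3 to 1502 and 2600 to 2990 CPM. Genes of the precursor stage differed less: Olig1 had a log2 fold change of 0.19 ± 0.14, Pdgfra -0.21 ± 0.33 and Olig2 -0.04 ± 0.17.

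No single gene passed at 48 h. EdgeR called 0 genes (smallest adjusted p 0.779), with 920 at an unadjusted p under 0.05. DESeq2 called 25 and limma-voom 0, voom with sample quality weights called 943, and edgeR without wt replicate 4 called 7, all lower. Knockout-labelled and wt libraries did not overlap in 5.28% of tested genes, against 1.59% by chance. Other lists that passed were BAF subunits (20 of 28 higher, median 0.09, adjusted p = 0.00825), cell cycle genes (24 of 28 lower, median -0.56), complex V (15 of 18 lower, median -0.40) and fatty acid oxidation (12 of 18 higher, median 0.08). Their adjusted p with an estimated correlation was 0.331 for BAF subunits and 0.853 for the other 3.

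**Figure D3:**
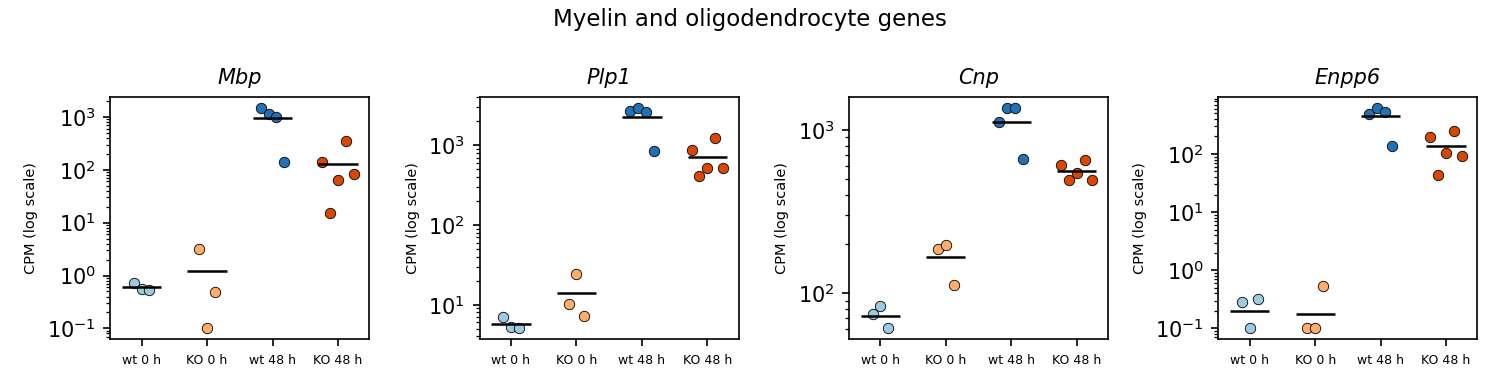
CPM on a log axis for 4 oligodendrocyte genes in wt and knockout-labelled (KO) libraries at 0 h and 48 h, with values under 0.1 drawn at 0.1. Points are libraries and bars are means. At 48 h Mbp averaged 948.0 in wt and 129.4 in KO libraries, and wt replicate 4 (138.7) lies among the KO libraries.

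The third comparison describes differentiation in wt cells. Cell cycle genes fell, and most oligodendrocyte markers, many astrocyte markers and some neuronal markers rose. With an estimated correlation the cell cycle list held (adjusted p = 0.0130), and those of the 3 cell types did not (adjusted p = 0.401, 0.437 and 0.532). Fry gave adjusted p of 1.5e-07 for cell cycle genes, 0.0011 for oligodendrocyte, 0.018 for astrocyte and 0.14 for neuronal markers. Of 28 cell cycle genes, 27 fell (28 adjusted over the list alone, median -3.98), including the replication helicase subunits Mcm4 (-2.88, adjusted p = 1.18e-07) and Mcm6 (-3.10). Nes, the progenitor intermediate filament, fell by 3.85 and Tnc by 2.34. Mbp rose by 10.56 (adjusted p = 0.000113), Gpr17 by 9.47 ± 0.28 (adjusted p = 1.83e-11), Gfap by 10.73 and Dcx, a microtubule protein of young neurons, by 6.11 on the log2 scale.

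In all, 1486 genes rose and 2161 fell. At 48 h Fa2h, an enzyme of myelin lipid synthesis, was at least 410-fold higher, Mobp at least 207-fold, Ptgs2 at least 190-fold and Slc14a1 at least 161-fold, each with no counts at 0 h. Enpp6 rose by 11.04. Entpd2 had 1 count at 0 h and a ratio of 1640 (interval 295 to 64900). Spp1 was at least 566-fold lower and Slc38a4 at least 155-fold, with no counts at 48 h, and Dhh was lower by a ratio of 922 (165 to 36500, 1 count at 48 h). Lgals1, a galectin, fell by 7.02 ± 0.44 (602.2 to 4.64 CPM, adjusted p = 9.62e-08), and Cpne7 (-6.88), Cd93 (-6.62), Adamts14 (-6.50) and Angpt2 (40.9 to 0.299 CPM) fell as well.

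Oligodendrocyte markers passed as higher with 12 of 16 up and 3 down, the same numbers adjusted over the list alone. Those that fell included Olig2 (-0.87), and Cnp rose by 3.95. Astrocyte markers passed with 10 of 18 up (14 adjusted over the list alone), such as Clu (5.82) and Aqp4 (8.18), and 1 down, Acsbg1 (-2.96). Neuronal markers passed with 7 of 24 up and 3 down, one of which was the growth cone protein Gap43 (-3.37). Progenitor markers did not pass (5 up, 6 down, adjusted p = 0.562), with a median of 0.12 and a mean of -0.29. BAF subunits did not pass as a list (adjusted p = 0.562), but 9 were called: Bcl7a rose by 0.83 and Smarcc2 by 0.51, and Actl6a, an actin-related subunit of progenitor complexes, fell by 1.04 and Brd7 by 0.71.

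Part of the genes of protein synthesis and energy metabolism fell, and none of these lists held with an estimated correlation (adjusted p of 0.197 or more). By fry the adjusted p was 0.0057 for cytosolic and 0.0015 for mitochondrial ribosomal proteins and 3.2e-05 for the TCA cycle. Fry gave 0.0040 for OXPHOS complexes II and III, 0.015 for V, 0.16 for I and 0.22 for IV. In wt falls were called for 50 of 83 cytosolic ribosomal proteins (59 adjusted over the list alone, median -0.71), such as Rps27l (-1.78), and for 16 of 79 mitochondrial ribosomal proteins (median -0.62). They were also called for 15 of 21 TCA cycle genes, such as Idh2 (-1.64), with 1 member higher. Of the OXPHOS subunits, 4 of 36 in complex I, 6 of 13 in II and III and 6 of 18 in V fell, among them Atp5b (-1.13, adjusted p = 0.000111). Adjusted p with an estimated correlation was 0.401 for both ribosomal lists and complexes II and III, 0.197 for the TCA cycle, 0.654 for complex I and 0.437 for V. Complex IV (adjusted p = 0.0643) and fatty acid oxidation (median 0.15, adjusted p = 0.685) did not pass. Glycolysis passed as lower with 9 of 24 down, such as Ldha (-2.16), and 3 up, such as Aldoc (1.88). P53 targets (10 of 17, Cdkn1a -3.50), immediate early (4 of 14), integrated stress response (6 of 20), antioxidant (6 of 18, 1 up) and mitochondrial biogenesis genes (3 of 25) passed as lower. BMP and TGF-beta genes passed as higher (5 up, 2 down, with Bmp7 -2.96), as did histones (4 up, 1 down) and the GABAergic list (1 up). The adjusted p with an estimated correlation was 0.532 for immediate early, GABAergic, mitochondrial biogenesis, BMP and TGF-beta, antioxidant, integrated stress response and glycolysis genes, 0.437 for histones and 0.401 for p53 targets. The count was 9671 with only the 7 libraries compared and 5818 without knockout-labelled 0 h replicate 2, a library outside this comparison that enters it through the shared spread, scaling and filter. With consecutive sample numbers as blocks of 12 libraries it was 1825.

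The fourth comparison follows differentiation in knockout-labelled cells. Cell cycle genes fell and glial markers rose here too: 27 of 28 cell cycle genes fell (median -4.13), 12 of 16 oligodendrocyte markers rose and 1 fell, and 10 of 18 astrocyte markers rose and 2 fell. Their adjusted p with an estimated correlation was 0.0203, 0.306 and 0.501 in that order, and by fry 1.2e-07, 0.00048 and 0.012. Gpr17 rose by 6.11 ± 0.23 (SE, adjusted p = 7.67e-10), Plp1 by 5.67, and Smarcc2 by 1.14, and Gja1, an astrocyte gap junction protein, rose from 116.8 to 706.2 CPM. Among progenitor genes, Vim fell by 1.78 and Fabp7 by 1.40.

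Here 1374 genes rose and 2418 fell. With no counts at 0 h, Igsf1 was at least 187-fold higher, Lgi4 at least 128-fold, Daw1 at least 98.3-fold, Hmgcs2 at least 90.5-fold and Tmem151a at least 66.0-fold. Enpp6 rose by 9.40 and Gpr149 by 7.70, and Zfp804a had a ratio of 259 (interval 71.4 to 2140, 2 counts at 0 h). Dhh was at least 279-fold lower, Lgals1 fell by 7.40 (adjusted p = 1.85e-08), and Xkr5 (-7.39), Tcim (-7.02), Mnd1 (-6.97), Chrm3 (-6.61) and Depdc1a (-6.28) fell as well, and Kcnc4 was lower by a ratio of 189 (64.1 to 922, 3 counts at 48 h).

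Ribosomal and metabolic lists fell in these cells too, and cytosolic ribosomal proteins had the smallest p of all lists (adjusted p = 2.70e-36, but 0.116 with an estimated correlation). Falls were called in 70 of 83 cytosolic ribosomal proteins (72 adjusted over the list alone, median -1.14, Rpl8 -1.33), 43 of 79 mitochondrial ribosomal proteins and 18 of 21 TCA cycle genes (median -0.89, Pdha1 -1.81). Of the OXPHOS subunits, 24 of 36 in complex I (median -0.84, Ndufv2 -1.49), 12 of 13 in II and III, 8 of 14 in IV and 16 of 18 in V fell. With an estimated correlation the TCA cycle held (adjusted p = 0.0413), and the adjusted p was 0.0814 for mitochondrial ribosomal proteins, 0.228 for complex I, 0.0550 for II and III, 0.471 for IV and 0.0945 for V. Glycolysis (9 down, 4 up), p53 targets (9 of 17 down), integrated stress response (7 down) and antioxidant genes (6 down, 2 up) passed as lower, and neuronal (5 up, 1 down) and synaptic genes (7 up, 1 down) as higher. Their adjusted p with an estimated correlation was 0.400, 0.247, 0.590, 0.590, 0.590 and 0.613 in that order. By fry the adjusted p was 0.0181 or less for the ribosomal, TCA cycle and OXPHOS subunit lists, and 0.0772 for synaptic genes. The count was 1683 with only the 8 libraries compared, 6938 without the 2 libraries with the fewest genes and 1617 with the blocks.

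Both genotypes shared 904 genes that rose (111.1 by chance) and 1572 that fell (284.4), and 2 went opposite ways. Across genes, which are not independent replicates, the time effects had r = 0.684. Other scalings changed the balance in both genotypes: upper-quartile factors moved the median of all genes from 0.10 to 0.27 in wt and from 0.15 to 0.30 in knockout-labelled cells, and the share of called genes that rose from 40.7% to 53.3% and from 36.2% to 47.4%. Levels here are relative to the TMM scale.

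**Figure D4:**
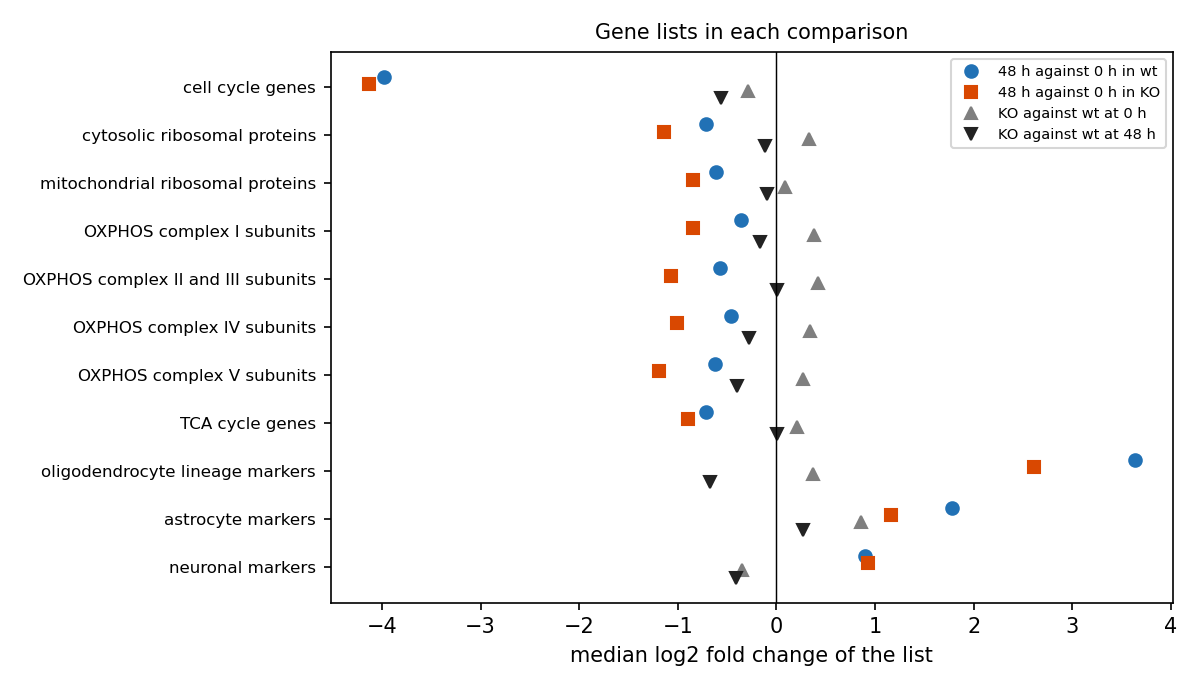
Median log2 fold change of 11 gene lists (horizontal axis) in 4 comparisons, drawn as separate symbols for wt and knockout-labelled (KO) libraries. Cell cycle genes fell with time (medians -3.98 in wt and -4.13 in KO). OXPHOS and ribosomal lists lie further below 0 with time in KO than in wt, and their higher medians in KO at 0 h are part of that difference.

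The fifth comparison tests whether the response to differentiation differed between genotypes. The rise of oligodendrocyte genes was smaller in knockout-labelled cells for Gpr17 (difference -3.35 ± 0.28, SE, adjusted p = 5.67e-05), Sox10 (-3.92 ± 0.62, adjusted p = 0.0372) and Cnp (-2.20 ± 0.34, adjusted p = 0.0372). Id4 (-2.84) and the receptor kinase Tyro3 (-1.60) also had negative differences, and Myc a positive one (1.66 ± 0.22, adjusted p = 0.0172). Gpr17, Sox10, Id4 and Myc already differed at 0 h, and Cnp was at 72.9 and 166.1 CPM at 0 h and 1123 and 557.4 CPM at 48 h in wt and knockout-labelled cells.

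These 6 genes were all those called. OXPHOS complexes I (33 of 36 negative, median -0.54), II and III (13 of 13, -0.51), IV (13 of 14, -0.56) and V (18 of 18, -0.60), cytosolic ribosomal proteins (76 of 83, -0.46) and fatty acid oxidation genes (17 of 18, -0.39) passed as lists of negative differences. So did TCA cycle, mitochondrial ribosomal, mitochondrial dynamics, Notch and oligodendrocyte genes, and BAF subunits passed as positive (21 of 28, median 0.26). The OXPHOS and ribosomal differences include the genotype effect at 0 h. Its median was 0.38 at 0 h and -0.17 at 48 h for complex I, 0.33 and -0.12 for cytosolic ribosomal proteins, and 0.27 and -0.40 for complex V. A length and level trend may account for the 0 h part. Adjusted p with an estimated correlation was at least 0.366 for every list. By fry the adjusted p of every list was at least 0.175 here, 0.16 at 0 h and 0.310 at 48 h. DESeq2 called 245 genes and limma-voom 1, blocks of consecutive sample numbers gave 0, and leaving out single libraries gave 1 to 341 (341 without knockout-labelled 0 h replicate 3, 13 without wt 48 h replicate 4).

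The genotype effects at 0 h and 48 h had r = 0.140 across genes, and with 0 calls at 48 h no called gene was shared. The r was 0.050 without knockout-labelled 0 h replicate 2, 0.081 without replicate 3 and 0.038 without the 2 libraries with the fewest genes. With a term for Y-linked transcripts it was 0.449, but both genotype effects then share the estimate of that term. Such sharing raises r by itself, so that value is not comparable. The size of r is not settled. The wt differentiation effect and the genotype effect at 48 h had r = -0.084 when the 4 wt libraries at 48 h were split 2 and 2 so that no library was shared, and r = -0.162 with shared libraries. In simulated data without effects, with the spread of all 15 libraries, the split gave -0.001 and the shared design -0.488. The covariance with shared libraries was -0.163, against a mean of -0.296 in that simulation and -0.072 in one with the spread of wt libraries. The real value lies between the 2. With no library shared the covariance was still -0.091, against -0.001 and 0 in the same 2 simulations. This argues against the shared libraries as the whole account of the negative relation. Of the genes called at 0 h, 68 of the 79 higher also rose with differentiation in wt and 13 of the 15 lower also fell, with 0 opposite. These comparisons share the wt libraries at 0 h, which raises such an overlap without a common cause, and it was not tested. The time effect in knockout-labelled cells shares the knockout-labelled 0 h libraries instead, which works against overlap. There, 42 of the 79 higher genes also rose (5.9 by chance) and 2 of the 15 lower also fell (2 by chance). Across all genes the 0 h genotype effect and the wt time effect had r = 0.270 (0.425 without knockout-labelled replicate 2). Simulated data without effects, with the spread of all 15 libraries, gave 0.541 (0.486). The covariance of 0.429 with all libraries was above the highest simulated value of 0.422. Without replicate 2 it was 0.411, below the highest of 0.419. Both were above the 0.112 of a simulation with the spread of wt libraries. The measured variance of the shared wt mean was 0.116, against 0.401 in the first simulation, which thus overstated what sharing adds.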

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

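Among the tests in this part, the counts of other splits, the test of replicate 2 for the genes called at 0 h, the tests of other single libraries, the calls made anew, and the second simulation were chosen after the result was seen. Splits were first counted in fits of only the libraries compared, where edgeR called 0 genes at 0 h, and were changed after this was seen to the model of all 15 libraries used for the calls.

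Differentiation responses differed between genotypes by the interaction term for Myc (1.66), Sox10 (-3.92), Gpr17 (-3.35), Id4 (-2.84), Cnp (-2.20) and Tyro3 (-1.60), as log2 differences. Lists that differed by the same term had medians of 0.263 for BAF subunits, -0.84 for oligodendrocyte markers, -0.537, -0.508, -0.56 and -0.595 for OXPHOS complexes I, II and III, IV and V, -0.417 for mitochondrial dynamics, -0.237 for mitochondrial ribosomal proteins, -0.458 for cytosolic ribosomal proteins, -0.249 for the TCA cycle, -0.388 for fatty acid oxidation and -0.454 for Notch genes. None of these lists held with an estimated correlation (adjusted p of at least 0.366). Of 100 splits of the libraries within each time, 5 gave at least the 6 genes called (highest other 22), so chance cannot be excluded for that count.

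The first pattern is the set of 94 genes called at 0 h. Without knockout-labelled replicate 2 the median change of these genes was 83.3% of that with it (log2 1.43 to 1.19), and among the 5 libraries without Y-linked transcripts it was 105.7%, but these genes were picked with the same libraries, which fixes much of both values. Genes called anew numbered 39 without replicate 2 (32 of the 94 among them), which argues against that library as the whole cause. They were 58 higher and 13 lower without the Y-linked libraries, but the knockout-labelled ones left at 0 h were replicates 2 and 3. That check leans on replicate 2, with few genes detected, and does not decide on the sex of the cells. A candidate explanation is that knockout-labelled cells at 0 h lay further along differentiation: their effect had a covariance with the wt differentiation effect of 0.429, and 0.411 without replicate 2. By the criterion written beforehand this failed without replicate 2, since simulated libraries without effects, with the spread of all 15, reached 0.422 and 0.419, and their r of 0.541 and 0.486 was above the real 0.270 and 0.425. A second simulation with the spread of the wt libraries reached 0.112 in both cases. The measured variance of the shared wt mean, which is what sharing adds, was 0.116, against 0.401 in the first simulation. The first simulation thus overstated the part due to sharing, and its r is no fair reference for the real one. The covariances argue against shared libraries as the whole cause. Whether the cells lay further along differentiation stays open, as does a difference by genotype. The 3 against 3 libraries allow 10 splits, too few for a share under 0.05 (1 split as large, the real one with 94 genes, and the highest other 1).

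The second pattern is the rise of OXPHOS and cytosolic ribosomal protein genes at 0 h, with 150 of 164 members higher and a median of 0.354. Without knockout-labelled replicate 2 the median was 106% of that with it, which argues against that library as the whole cause. It was 0.451 without replicate 3 and 0.258 to 0.405 without single wt libraries, but 0.18 without replicate 1, where the complex IV list also reversed (mean -0.452), so replicate 1 carries part of the pattern. The median of the members lay 0.478 above that of all tested genes. Relative to a trend on transcript length and mean level, fitted to other protein-coding genes, their median was -0.0644. This is -13.5% of the first value, though the 2 values have different references. Over protein-coding genes the 0 h effect was only weakly related to length alone (Spearman -0.0917). A length and level trend may therefore account for the whole pattern, and what made the trend was not tested. A difference by genotype stays open as well.

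The third pattern is the lower level of oligodendrocyte lineage genes at 48 h, with a median of -0.67. Without knockout-labelled replicate 2 the median was 100.9% of that with it, and leaving out any 1 library at 48 h gave -0.57 to -0.91. This argues against replicate 2 alone as the whole cause. Among the 6 libraries without Y-linked transcripts the median was 127.7%, but the knockout-labelled ones there were only replicates 2 and 3. Replicate 2 had few genes detected and the lowest Mbp of its group (15.3 CPM). The check thus rests largely on replicate 3 and does not decide on the sex of the cells. Mature genes (Mbp, Plp1, Cnp, Mag, Mog) had a median of -1.68 and precursor genes (Pdgfra, Cspg4, Olig1, Olig2) of 0.07. The difference was -1.748, with an SE of 0.832 built from those of single genes. By the criterion written beforehand this went against a smaller share of all lineage cells. But wt cells at 0 h already held Olig1 at 715.1 to 1026, Olig2 at 630.9 to 774.1 and Cspg4 at 53.7 to 93.4 CPM. These genes therefore do not count the cells that entered the lineage, and the test cannot decide. Slower maturation in knockout-labelled cultures stays open, as does variation between cultures, since wt replicate 4 held Mbp at 138.7 CPM. For genes called at 48 h, 100 of 100 splits gave at least the 0 of the real one, as any split must, so this says nothing about chance. The highest other of 42 points to some structure of the samples, and which one was not tested.

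Differentiation counts were larger than in any other split: in wt 1 of 35 splits gave as many as the 3647 genes (the real one, highest other 353), and in knockout-labelled cells 1 of 56 gave as many as the 3792 (highest other 468). Both shares are under 0.05 and are the smallest that so many splits allow. They make a random grouping unlikely but do not exclude it, and they treat the libraries as separate cultures.

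At 48 h, 24 values stood far from the other libraries of their group, among 196 groups of values tested. Chance alone would give about 9.8 in normally distributed values, which CPM values need not be. Any value above 0 is flagged where the other libraries are at 0, so no excess over chance is read from this. In wt replicate 4, Ndrg2 (678.7 CPM) and Vim (997.8 CPM) were above the other wt libraries (496.6 to 525.1 and 635.4 to 645.4 CPM), and Bcas1 (442.1 CPM), Gap43 (9.45 CPM) and Tmem151a (0.927 CPM) were below them. Dhh was at 0.0927 CPM there and at 0 in the rest. In other wt libraries, Id4 was low in replicate 3 (194.9 CPM), Bmp7 high in replicate 1 (15.2 CPM) and Eif2s3y at 0.168 CPM in replicate 2. Knockout-labelled replicate 2, with few genes detected, was high in Id4 (303.8 CPM), Lgals1 (12.2 CPM), Cd93 (9.88 CPM), Nes (538.7 CPM), Bmp7 (39.97 CPM) and Tmem151a (9.25 CPM), and low in Hes5 (22.9 CPM), Gap43 (0 CPM) and Fbln1 (0 CPM). Replicate 4 was high in Mobp (8.32 CPM), Angpt2 (1.23 CPM), Bmp4 (54.2 CPM) and Daw1 (9.17 CPM), replicate 3 in Xkr5 (0.240 CPM) and replicate 1 in Kcnc4 (0.168 CPM).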

How the results depend on the processing

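The fit without the 2 libraries with the fewest genes, the term for Y-linked transcripts, the robust fit and the same 12 libraries with no block were chosen after seeing the data. Counts of called genes are given in the order 0 h, 48 h, wt time, knockout-labelled time and interaction, and were 94, 0, 3647, 3792 and 6. DESeq2 called 779, 25 and 245 genes at 0 h, 48 h and in the interaction, limma-voom 29 at 0 h and 1 in the interaction, and voom with quality weights 6, 943 and 10710 in the first 3. A fit of only the groups compared called 0 genes at 0 h, 9671 in wt and 1683 in knockout-labelled time. The replicate block called 1825, 1617 and 0 in the last 3, and the same 12 libraries without it 2338 in knockout-labelled time and 1 in the interaction, so fewer samples account for part of that loss. No low-count filter gave 24 genes in the interaction. Without the 2 libraries with the fewest genes the counts were 279 at 0 h (87 of the 94 shared), 8444 in wt, 6938 in knockout-labelled time and 26 in the interaction. The term for Y-linked transcripts gave 248 at 0 h (92 shared) and 42 at 48 h. The cause was not tested for the others. Both other scalings, the abundance-file counts, the 2-fold threshold, the robust fit and removal of sex-linked genes kept all 5 counts within 1.5 times.

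Lists that passed at 48 h (5) became 14 with no filter, 9 with the stricter filter, 8 with only the groups compared, 14 with quality weights and 11 without the 2 libraries, and in wt time (19) 11 with the stricter filter. DESeq2, limma-voom, the robust fit and the 2-fold threshold gave no list tests. The correlation of genotype effects (0.140) became 0.194 with limma-voom, 0.078 with quality weights, 0.069 with no filter and 0.212 with the stricter filter. It was 0.105 by Spearman, 0.038 without the 2 libraries and 0.449 with the Y-linked term, whose estimate both effects share. The correlation of wt differentiation with the 48 h effect (-0.084) became -0.114 with replicates 1 and 3 and -0.054 with replicates 1 and 4 for differentiation. It was -0.038 with the stricter filter and -0.045 without the 2 libraries. The complex IV list at 0 h reversed without knockout-labelled 0 h replicate 1 (mean -0.452, adjusted p = 0.885, against 0.513 without replicate 3), and the cause was not tested.

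Leaving out single libraries gave 2 to 670 genes at 0 h. Those that moved this count over 1.5 times were wt 0 h replicates 1 (2), 2 (6) and 3 (16), knockout-labelled 0 h replicates 1 (173), 2 (39) and 3 (670), wt 48 h replicate 2 (46) and knockout-labelled 48 h replicates 1 (51), 2 (163) and 5 (56). The ranges were 0 to 7 at 48 h (7 without wt replicate 4), 2491 to 5818 in wt (5818 without knockout-labelled 0 h replicate 2), 3189 to 4711 in knockout-labelled time and 1 to 341 in the interaction. That last count was 1 without wt 0 h replicates 1 or 2, wt 48 h replicates 1 or 2 or knockout-labelled 48 h replicate 5, 2 without knockout-labelled 48 h replicates 1 or 3, 3 without wt 0 h replicate 3, 13 without wt 48 h replicate 4 and 341 without knockout-labelled 0 h replicate 3. Lists passed in 10 to 18 cases at 0 h (10 without knockout-labelled replicate 1), 3 to 12 at 48 h, 16 to 20 in wt, 12 to 18 in knockout-labelled time and 10 to 15 in the interaction. At 48 h they were 8 without knockout-labelled 0 h replicate 1, 3 without knockout-labelled 48 h replicates 1 or 3, 12 without replicates 2 or 4, 9 without wt replicate 1 and 11 without wt replicate 4. The first correlation ranged from 0.05 (without knockout-labelled 0 h replicate 2) to 0.176 and the second from -0.089 to -0.045 over 8 libraries. For named genes, of their alternatives, 8382 were on the same side of the threshold, 33 passed only in the alternative, 589 no longer passed and 0 reversed. For lists these were 5280, 141, 167 and 1.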

Other observations

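Among the tests in this part, none was chosen after the result it measures was seen, but the list of ribosome biogenesis factors was written after Myc, Gnl3 and Rrs1 had been called. The adjustment of its p over the 5 comparisons was added after the p was seen.

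Markers of other cell types ranged from near 0 to clearly present. The most abundant microglial markers, Cd68 and P2ry12, averaged at most 1.85 CPM in any group. The endothelial marker Pecam1 was at 17.0 CPM (SD 23.7) in knockout-labelled and 1.75 CPM in wt libraries at 0 h (adjusted p = 0.405), with 44.4 CPM in knockout-labelled replicate 3 at 0 h and 76.9 CPM in replicate 1 at 48 h. Fbln1, a fibroblast matrix gene, was at 63.6 CPM in wt at 0 h. Pdgfrb, a pericyte gene, had 3 counts in wt at 0 h and 55.0 CPM at 48 h, a ratio of 682 (interval 233 to 3310). Foxj1, a factor of ciliated ependymal cells, rose with time in wt from 11.7 to 38.4 CPM (adjusted p = 0.00284). Bmp4, with 1 count in wt at 0 h, reached 39.0 CPM at 48 h, a ratio of 1600 (287 to 63100). Pink1, a kinase of mitophagy, rose from 27.9 to 157.7 CPM in wt and from 50.6 to 202.5 CPM in knockout-labelled cells, although the mitochondrial dynamics list did not pass in either (adjusted p = 0.890 and 0.231). Lists of OXPHOS assembly factors, glutamatergic, Wnt, hedgehog, hypoxia, interferon, regional, endothelial, fibroblast, ependymal, microglial, pluripotency and sex-linked genes passed in no comparison. The sex-linked list had 3 members higher at 0 h and 4 at 48 h adjusted over the list alone.

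A hypothesis followed from the lower Myc at 0 h, that ribosome biogenesis factors, many of them targets of Myc, are lower as well. A list of 42 tested factors, which left out the called genes, was lower at 0 h by camera with an estimated correlation (p = 0.0163, or adjusted p = 0.0271), with 40 of 42 lower, a median of -0.69 and 0 called. Without knockout-labelled replicate 2 the median was -0.60. The list also fell with time in wt (adjusted p over the 5 comparisons = 0.0168 with an estimated correlation, 42 of 42 lower, 28 called), and in knockout-labelled cells by camera at the preset correlation (adjusted p = 0.000938) but not with an estimated one (adjusted p = 0.219, median -0.26, 31 of 42 lower, 12 called). At 48 h the genotype effect had adjusted p = 1.34e-05 at the preset correlation and 0.138 with an estimated one (median 0.12, 14 of 42 lower), and the interaction had adjusted p = 0.0168 with an estimated correlation and a median of 0.79. The adjusted p of this list is over the 5 comparisons, which is more lenient than the adjustment over 43 lists used elsewhere. At 0 h, progenitor markers and OXPHOS complexes II and III had unadjusted camera p of 0.0162 and 0.00893 with an estimated correlation. Over the lists, both had an adjusted p of 0.156. Lower ribosome biogenesis in undifferentiated knockout-labelled cells may go with lower Myc, or both may go with the stage of differentiation, which the test of this list does not separate.

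A second hypothesis was that sequence carried with the targeted locus changes genes beside Bcl7a. Of 257 tested genes within 10 Mb, 1 had the same direction and an unadjusted p under 0.05 at both times, against 138 of 18117 other genes, and Fisher's exact test (two-sided) gave p = 1. The genes near thus showed no excess (0.389% against 0.762%). Such low shares leave the test little power for a few changed neighbours, so it does not decide the question. Duplicated libraries were also checked for: between libraries of a group the median chi-square per gene was at least 2.18, against 0.455 for sampling noise alone.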
